A study of Chlorella sp. HS2 with 12 samples.

How the data were processed

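The authors deposited a matrix of expected counts, the read pairs that RSEM 1.3.2 assigned to each assembled gene after Bowtie alignment to a Trinity assembly. As deposited, these expected counts were not normalised. The deposited comparison table gives a mean signal per group, which the authors made by SVCD normalisation, a method that estimates the variation between samples. It also gives the authors' log2 fold changes of marine over freshwater at each phase and their difference, made with DESeq2 1.20.0. The adjusted p-values of that table come from the authors' same test, as deposited. Per the file headers, the annotation table holds the length in bases of 1 sequence per gene and the E-value of its best Swiss-Prot hit. RNA was selected by poly(A) and sequenced on an Illumina HiSeq as paired reads, per the labels, and library preparation kept no strand information.

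Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr by group, libraries were scaled with TMM factors, and 1 model with a mean per group was fitted to all 12 libraries in edgeR 4.0.16 under R 4.3.3. The quasi-likelihood F-test gave p-values, adjusted by the Benjamini-Hochberg method over 31491 genes. A gene was called at a false discovery rate (FDR) under 0.05. There were 5 contrasts: marine against freshwater in each phase, stationary against exponential in each medium, and the difference between the salt effects of the phases. Each group had 3 libraries, and 3 against 3 allows no exact permutation p, counting both tails, below 0.1. DESeq2 1.42.0 was run as another test. Reading of tables and drawing used Python 3.11.15 with matplotlib 3.10.9.

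A set of 32 gene lists was written as patterns over product names before the data were examined, as were the tests, the rule for named genes, a panel of 17 products and most alternatives. Lists with at least 5 tested genes, 30 of them, were tested with camera of limma 3.58.1, on both sides, with a preset correlation of 0.01. Camera compares a list with all other tested genes. Its p was adjusted over the lists of a comparison, and a list was called at an adjusted p under 0.05. Calls were set beside camera with an estimated correlation and beside fry, which tests whether the genes of a list move one way on balance. The lists covered photosynthesis (light harvesting, plastid-encoded genes, Calvin cycle, chlorophyll and carotenoid biosynthesis, DNA repair and photoprotection), carbon (glycolysis, tricarboxylic acid cycle, respiratory chain, oxidative pentose phosphate path, starch synthesis and degradation) and lipids (fatty acid synthesis and degradation, glycerolipid assembly). They also covered protein and stress (cytosolic and plastid ribosomes, translation factors, proteasome, heat shock, antioxidant, autophagy, compatible solutes), transport and nutrients (ion transport, nitrogen assimilation, phosphate uptake), the cell (DNA replication, histones, flagella), and markers of bacterial, animal and fungal cells. The animal and fungal marker lists had 4 and 2 tested genes and were not tested.

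Names and lineages departed from the plan. The plan named the deposited Trinotate report, but it holds no product names. Names were taken from the deposited Blast2GO table, with hits at an E-value of at most 1e-10, and lineages from a map of the 530 genera of those hits. That table shortens 167 names, and patterns for shortened names, written after it was seen, added 53 list members. Also chosen after the data were seen were the fit limited to genes detected in both media (15 or more counts in each), which leaves out the largest salt changes by construction, sums over assembly components and over lists, list tests under DESeq2 size factors and under scaling matched to the authors' table, and a test of the plastid-encoded list without 2 nuclear genes that its pattern took in.

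Named genes followed a fixed rule. Part 1 took, for at most 10 called lists with the smallest camera p, the 2 members with the smallest p in the direction of the list, with an FDR under 0.05 and a mean log2 CPM of at least 3. It is given in part, in order of p. Part 2 took the 5 highest and 5 lowest log2 fold changes among called genes with a mean log2 CPM of at least 4 and an E-value of at most 1e-20, without overlap of the groups in pairwise contrasts. Part 3 took the panel, for each product the matching gene with the highest mean; 16 products matched a tested gene and oxygen-evolving enhancer protein 1 did not.

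Where all libraries of a group had 0 counts, a fold is given as a lower bound against 3 counts over the group. Fitted folds of such genes depend on a prior count, so list medians are also given with these genes at their bound. With 1 to 3 counts, a ratio is given with its exact 95% counting interval. Intervals and floors cover counting error only. Libraries were to be merged if they agreed within counting noise, by a chi-square over its degrees of freedom of at most 1.5, and none did.

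The procedure was tested on simulated counts with 31491 genes, in which 200 genes were changed in the exponential salt comparison. With trended dispersions it recovered 2 of 50 genes changed 2-fold, 26 of 50 at 4-fold, 37 of 50 at 8-fold and 41 of 50 at 16-fold, with 3 false calls. With tagwise dispersions it recovered 4, 24, 33 and 45 of 50, also with 3 false calls. Changes of 8- and 16-fold were added after a first run with smaller changes recovered few genes. A list shifted 2-fold was found in both (adjusted p = 3.65e-27 and 1.72e-54), with 0 other lists called. In an unshifted comparison 0 and 1 lists were called. Most 2-fold changes were thus missed with 200 genes changed, but need not be with more.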

Results

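Poly(A)-selected RNA of Chlorella sp. HS2, a unicellular green alga, was sequenced after growth without added sea salt, in freshwater medium, or with 3% (w/v) sea salt, in marine medium. Cultures were taken 4 days after inoculation, in exponential phase, and 6 days after inoculation, in stationary phase, which gave 4 groups of 3 libraries. The series describes the 3 samples of each condition as biological replicates. Library totals ran from 9378066 to 11280635 estimated counts. The genes come from an assembly made without a reference genome, so no genomic positions are given. Each gene carries its assembly identifier and the name of its best Swiss-Prot hit. In all, 31491 genes passed the filter on low counts and were tested. Levels below are CPM, TMM-normalised counts scaled to a common library size, as mean ± SD of n = 3 libraries, and log2 fold changes stand with their standard errors.

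Reads with a Viridiplantae best hit made up 48.6% ± 2.27 of counts in freshwater exponential libraries (n = 3), 38.5% ± 0.582 in freshwater stationary, 44.8% ± 0.226 in marine exponential and 41.1% ± 1.77 in marine stationary libraries. Bacterial hits held 3.44% ± 0.342, 3.29% ± 0.202, 2.42% ± 0.0443 and 2.07% ± 0.0932 in the same order. With 3 libraries against 3 the exact permutation test, counting both tails, cannot go below p = 0.1, and of 32 such lineage tests none had a Benjamini-Hochberg adjusted p below 0.139. A set of 16699 genes was detected in freshwater libraries only and 12183 genes in marine libraries only, at 15 or more counts summed over the 6 libraries of a medium, a limit set after the data were seen. Freshwater-only genes took 2.85% ± 1.33 of counts in freshwater exponential and 6.94% ± 2.14 in freshwater stationary libraries, and marine-only genes took 2.80% to 2.87% in marine exponential and 6.03% to 6.38% in marine stationary libraries. Only 6.21% of marine-only genes had a hit, and of those hits 55.1% (417 of 757) were bacterial and 10.2% from Viridiplantae, against 6.37% and 55.6% of hits of genes of both media. Of hits of freshwater-only genes 2043 of 4319 were from animals and 994 from Viridiplantae, against 1359 and 2689 of 4836 for genes of both media.

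**Figure D1:**
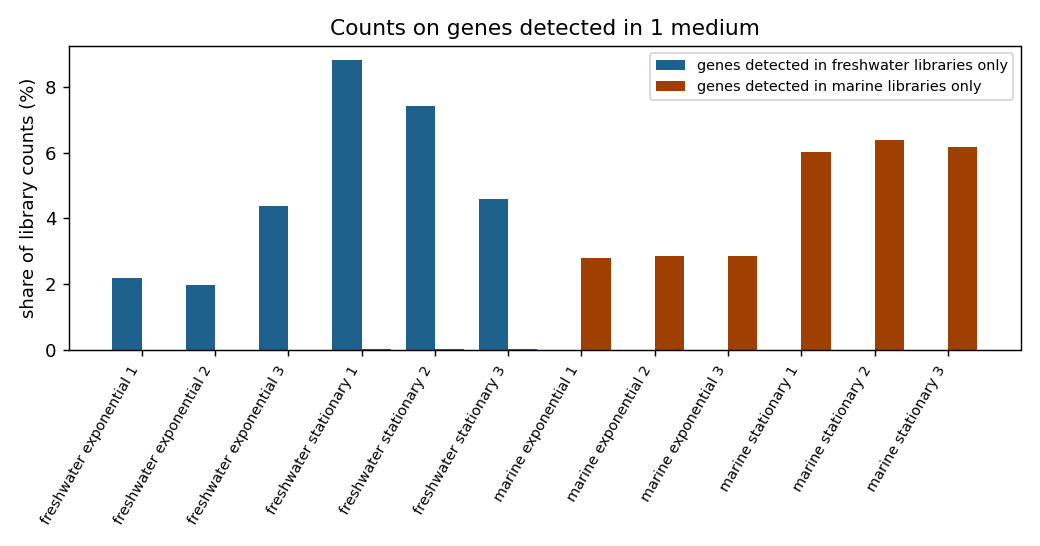
Share of each library's counts, in percent, on genes detected in freshwater libraries only and in marine libraries only, 1 pair of bars per library. Freshwater-only genes took between 1.97% and 8.80% of counts in the 6 freshwater libraries.

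The 3 marine exponential libraries, and marine stationary replicates 1 and 2, carry library codes that share a stem, and they lay closer together than other replicates. Their median absolute log2 differences ran from 0.143 to 0.173, against 0.345 to 0.564 between freshwater replicates and 0.691 and 0.700 between those marine stationary libraries and replicate 3. None of these pairs agreed within counting noise, a rule that repeat preparations of 1 culture would fail too, so it does not show separate cultures. All 12 libraries were kept as the series describes them. If those with a shared stem share a culture, p-values in marine comparisons measure in part a technical spread. Summing those with a shared stem leaves 1 marine exponential and 2 marine stationary samples. The spread of marine exponential cultures is then borrowed from other groups, so counts from these sums are given but not read as tests of a result.

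The first comparison asked how salt altered the transcriptome in exponential phase. Photosynthesis genes were far lower in marine medium. Chlorophyll a-b binding protein 6A (TRINITY_DN1819_c0_g1), an antenna protein, fell from 2394 ± 140 to 24.2 ± 3.05 CPM and the Rubisco small subunit (TRINITY_DN1599_c0_g1), part of the enzyme that fixes CO2, from 9946 ± 948 to 805 ± 31.7 CPM. Citrate synthase (TRINITY_DN865_c0_g1), which opens the tricarboxylic acid cycle, fell from 5428 ± 81.0 to 503 ± 17.8 CPM. Nitrate reductase (TRINITY_DN580_c1_g1) rose from 385 ± 138 to 8491 ± 447 CPM, and granule-bound starch synthase 1 (TRINITY_DN2954_c0_g1), which makes amylose, from 87.7 ± 15.6 to 628 ± 34.7 CPM. In all, 2928 genes were called higher and 3392 lower in marine medium. The balance turned over genes of both media (2454 higher, 2074 lower), with only the 6 compared libraries fitted (3683 and 3108) and without freshwater stationary replicate 1 (2451 and 2235).

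Of the 39 tested light-harvesting and nuclear photosystem genes 26 were lower, 1 higher and 12 not called in marine exponential libraries. Adjusted over the list alone, 26 were lower and 2 higher. Their median log2 fold change was -4.12 (-4.41 with genes of a group at 0 placed at their bound; camera adjusted p = 1.37e-19, and adjusted p = 0.0372 with an estimated correlation). Chlorophyll a-b binding protein 6A had a log2 fold change of -6.63 ± 0.26 (FDR 2.51e-07). Among 17 plastid-encoded photosynthesis genes 9 were lower, 0 higher and 8 not called, and 10 were lower adjusted over the list alone (median -3.03, adjusted p = 1.2e-07, and adjusted p = 0.0951 with an estimated correlation). Here the Rubisco large chain (TRINITY_DN1417_c0_g4) fell from 42.1 ± 11 to 1.38 ± 0.393 CPM, a log2 fold change of -4.92 that was -0.93 for its summed assembly component. Without 2 nuclear cytochrome b6-f iron-sulfur subunit genes the list median was -3.21 (adjusted p = 1.52e-07). Effects of poly(A) selection on plastid or bacterial RNA were not tested. The 17 Calvin cycle genes had 9 lower, 1 higher and 7 not called, with the same counts adjusted over the list alone (median -1.0, adjusted p = 0.000354, and adjusted p = 0.108 with an estimated correlation).

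**Figure D2:**
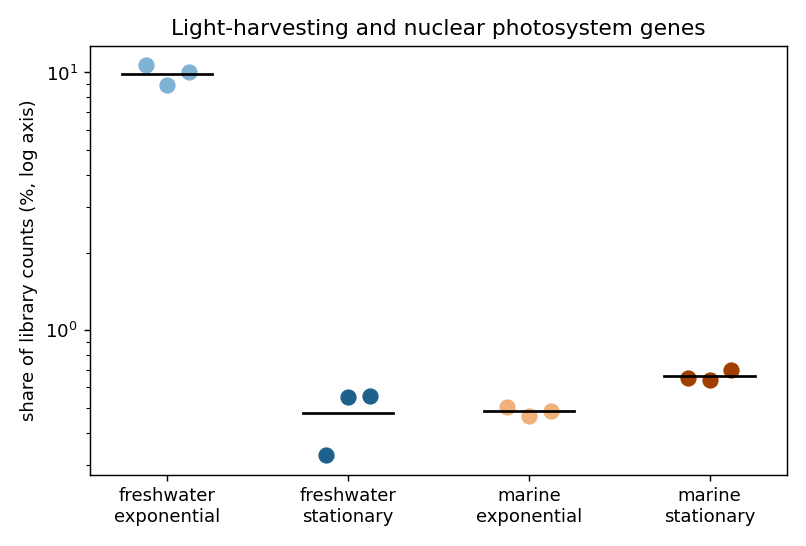
Share of counts on light-harvesting and nuclear photosystem genes in each library, in percent on a log axis, with points for the 3 libraries of a group and a line at their mean. Freshwater exponential libraries held 8.94% to 10.7%, and the other 9 libraries 0.327% to 0.701%.

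Many protein synthesis genes were lower as well. With salt the 209 cytosolic ribosomal protein genes together fell from 153826 ± 19678 to 97191 ± 5417 CPM (11.4% and 11.2% of counts). Of 186 tested 116 were lower, 2 higher and 68 not called. Adjusted over the list alone, 125 were lower and 3 higher (median -2.99, or -3.0 at bounds, adjusted p = 7.37e-35). Ribosomal protein L21-2 (TRINITY_DN3150_c0_g4) fell from 1844 ± 200 to 825 ± 41.3 CPM, and S28 (TRINITY_DN4398_c0_g1), detected in freshwater only, was at least 344-fold lower. Of these 186 genes 80 were detected in freshwater only, and over the 106 detected in both media the median was -0.84 (adjusted p = 3.19e-08, and adjusted p = 0.0643 with an estimated correlation). Translation factors had 35 of 77 lower, 6 higher and 36 not called, with 45 lower and 6 higher adjusted over the list alone (median -1.63, or -1.68 at bounds, adjusted p = 2.67e-09). In this list 33 genes were detected in freshwater only, and over the 43 found in both media the call was lost (median -0.36, adjusted p = 0.0587). Plastid ribosomal proteins had 10 of 16 lower, 0 higher and 6 not called, also adjusted over the list alone (median -2.43, or -2.37 at bounds, adjusted p = 5.28e-10, and adjusted p = 0.0951 with an estimated correlation).

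Respiratory genes followed. The tricarboxylic acid cycle list had 26 of 43 lower, 2 higher and 15 not called, with 31 lower and 4 higher adjusted over the list alone (median -1.3, adjusted p = 5.28e-10). Citrate synthase changed by -3.43 ± 0.18 (FDR 9.96e-07). Respiratory chain genes had 27 of 74 lower, 2 higher and 45 not called, with 33 lower and 2 higher adjusted over the list alone (median -1.78, or -1.86 at bounds, adjusted p = 5.28e-10). Heat shock proteins and chaperones had 26 of 70 lower, 10 higher and 34 not called, with 33 lower and 13 higher adjusted over the list alone (median -1.66, adjusted p = 0.000634). In that list 28 genes were freshwater only, and over the 42 found in both media the median was -0.07 (adjusted p = 0.655). These 3 lists, cytosolic ribosome and translation factors kept their calls with an estimated correlation (adjusted p from 0.0308 to 0.0489). Over genes found in both media none of the 5 did (adjusted p from 0.0575 to 0.748), and the respiratory chain median was -0.91.

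Nitrogen assimilation, starch and osmolyte lists were higher in marine medium. Nitrogen assimilation had 12 of 26 higher, 2 lower and 12 not called, with 12 higher and 3 lower adjusted over the list alone (median 1.3, or 1.16 at bounds, adjusted p = 0.00146, and adjusted p = 0.0569 with an estimated correlation). Its counts summed to 2099 ± 71.9 CPM in freshwater exponential and 12498 ± 527 CPM in marine exponential libraries, of which the nitrate reductase gene TRINITY_DN580_c1_g1 held 385 and 8491 CPM. That gene changed by 4.46 ± 0.41 (FDR 3.27e-05) and the urea-proton symporter DUR3 (TRINITY_DN139_c0_g2) by 7.36 ± 0.50 (FDR 4.55e-06), although the summed genes of its assembly component changed by -0.77. Compatible solute genes had 14 of 26 higher, 4 lower and 8 not called, with 16 higher and 4 lower adjusted over the list alone (median 0.66, mean -0.28, adjusted p = 0.00209, and adjusted p = 0.119 with an estimated correlation). Glutamate 5-kinase (TRINITY_DN3484_c0_g1), on the path to proline, rose from 32.7 ± 2.59 to 88.3 ± 3.09 CPM, and glycerol-3-phosphate dehydrogenase (TRINITY_DN3869_c0_g1), on the path to glycerol, from 45.8 ± 2.35 to 105 ± 6.28 CPM. Starch synthesis had 8 of 13 higher, 1 lower and 4 not called (8 and 2 adjusted over the list alone, median 0.58, adjusted p = 0.0037, and adjusted p = 0.153 with an estimated correlation). Starch degradation had 9 of 15 higher, 3 lower and 3 not called (9 and 4 adjusted over the list alone, median 0.99, adjusted p = 0.0152, and adjusted p = 0.108 with an estimated correlation).

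Fits without 1 library tested more genes, and some lost these calls of higher lists. Compatible solutes lost theirs without any 1 of 7 libraries, 2 of them freshwater stationary (adjusted p up to 0.178). Nitrogen assimilation lost it without freshwater exponential replicate 1 (adjusted p = 0.115) or freshwater stationary replicate 3 (adjusted p = 0.0508), starch synthesis without freshwater exponential replicate 3 (adjusted p = 0.0629), and starch degradation without freshwater exponential replicates 1 or 2 or marine exponential replicates 1 or 3 (adjusted p up to 0.104).

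A last 4 lists were called lower with an adjusted p nearer the threshold. Flagella and basal body genes, which include dyneins and tubulins, had 23 of 132 lower, 13 higher and 96 not called (24 and 14 adjusted over the list alone, median -4.32, or -2.33 at bounds, adjusted p = 0.0042, and adjusted p = 0.327 with an estimated correlation). Proteasome genes had 19 of 71 lower, 9 higher and 43 not called (28 and 13 adjusted over the list alone, median -1.83, or -1.48 at bounds, adjusted p = 0.0414, and adjusted p = 0.553 with an estimated correlation). This call was lost without marine stationary replicate 3 (adjusted p = 0.053). Detected in freshwater only were 87 of these flagella and 36 of these proteasome genes, and over genes found in both media the medians were 0.34 and 0.29 (adjusted p = 0.099 and 0.0488, and 0.411 and 0.606 with an estimated correlation). Antioxidant genes had 17 of 51 lower, 7 higher and 27 not called (21 and 7 adjusted over the list alone, median -0.53, adjusted p = 0.0316, and adjusted p = 0.0717 with an estimated correlation). Fatty acid degradation had 10 of 23 lower, 4 higher and 9 not called (12 and 4 adjusted over the list alone, median -1.32, adjusted p = 0.0197, and adjusted p = 0.224 with an estimated correlation). Over genes found in both media these had medians of 0.05 (adjusted p = 0.327) and -0.33 (adjusted p = 0.273).

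Among single genes of high expression, a peroxisomal primary amine oxidase (TRINITY_DN147_c0_g1) was seen in marine medium only, at 596 ± 15.9 CPM and at least 4354-fold higher, although its summed component, also present in freshwater, changed by 1.93. The kinase TOUSLED (TRINITY_DN425_c0_g1) rose from 31.1 ± 8.23 to 10759 ± 22.9 CPM, a dynein regulatory complex protein (TRINITY_DN2871_c0_g4) from 3.15 ± 0.377 to 401 ± 4.13 CPM and a septin-3 hit (TRINITY_DN1749_c0_g1) from 0.781 ± 0.197 to 88.8 ± 2.31 CPM. The 5 lowest fold changes belonged to freshwater-only genes, among them ribosomal protein S21 (TRINITY_DN2094_c0_g1) at least 1475-fold, an aldolase (TRINITY_DN5745_c0_g3) at least 1364-fold, L14 (TRINITY_DN3056_c0_g1) at least 751-fold and S27 (TRINITY_DN3094_c0_g1) at least 717-fold lower. Of the gene panel fixed beforehand, glucose-6-phosphate 1-dehydrogenase (TRINITY_DN769_c0_g1), which feeds the oxidative pentose phosphate path, rose from 195 ± 15.9 to 1509 ± 19.3 CPM. Stearoyl-ACP desaturase (TRINITY_DN986_c0_g1) fell from 839 ± 160 to 183 ± 2.33 CPM and chlorophyll a-b binding protein 3 (TRINITY_DN2252_c0_g2) from 65219 ± 5937 to 1450 ± 102 CPM. Calls of ascorbate peroxidase (TRINITY_DN247_c0_g1; 175 ± 16 against 313 ± 44.4 CPM), diacylglycerol acyltransferase (TRINITY_DN290_c3_g2; 30.9 ± 4.81 against 51.5 ± 1.69 CPM), ADP-glucose pyrophosphorylase (TRINITY_DN86_c0_g1; 357 ± 29.1 against 556 ± 22.7 CPM) and a sodium/hydrogen exchanger (TRINITY_DN832_c0_g1; 209 ± 65.9 against 434 ± 54.1 CPM) were not kept in all fits that left out 1 library. They were lost without any 1 of 5, 7, 8 and 7 libraries, at an adjusted p of up to 0.132, 0.218, 0.251 and 0.226. Biotin carboxylase (TRINITY_DN3334_c0_g3; FDR 0.0825), superoxide dismutase (TRINITY_DN1132_c0_g1; FDR 0.361) and the plasma membrane proton ATPase (TRINITY_DN298_c2_g1; FDR 0.963) were not called. With assembly components summed, the calls of ADP-glucose pyrophosphorylase and the exchanger were lost (adjusted p = 0.0623 and 0.072). Diacylglycerol acyltransferase changed by -0.17 (adjusted p = 0.604), superoxide dismutase was called lower (-0.88, adjusted p = 0.00373), and the log2 fold changes of glutamate 5-kinase and the aldolase TRINITY_DN5745_c0_g3 were 0.70 and -4.11.

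**Figure D3:**
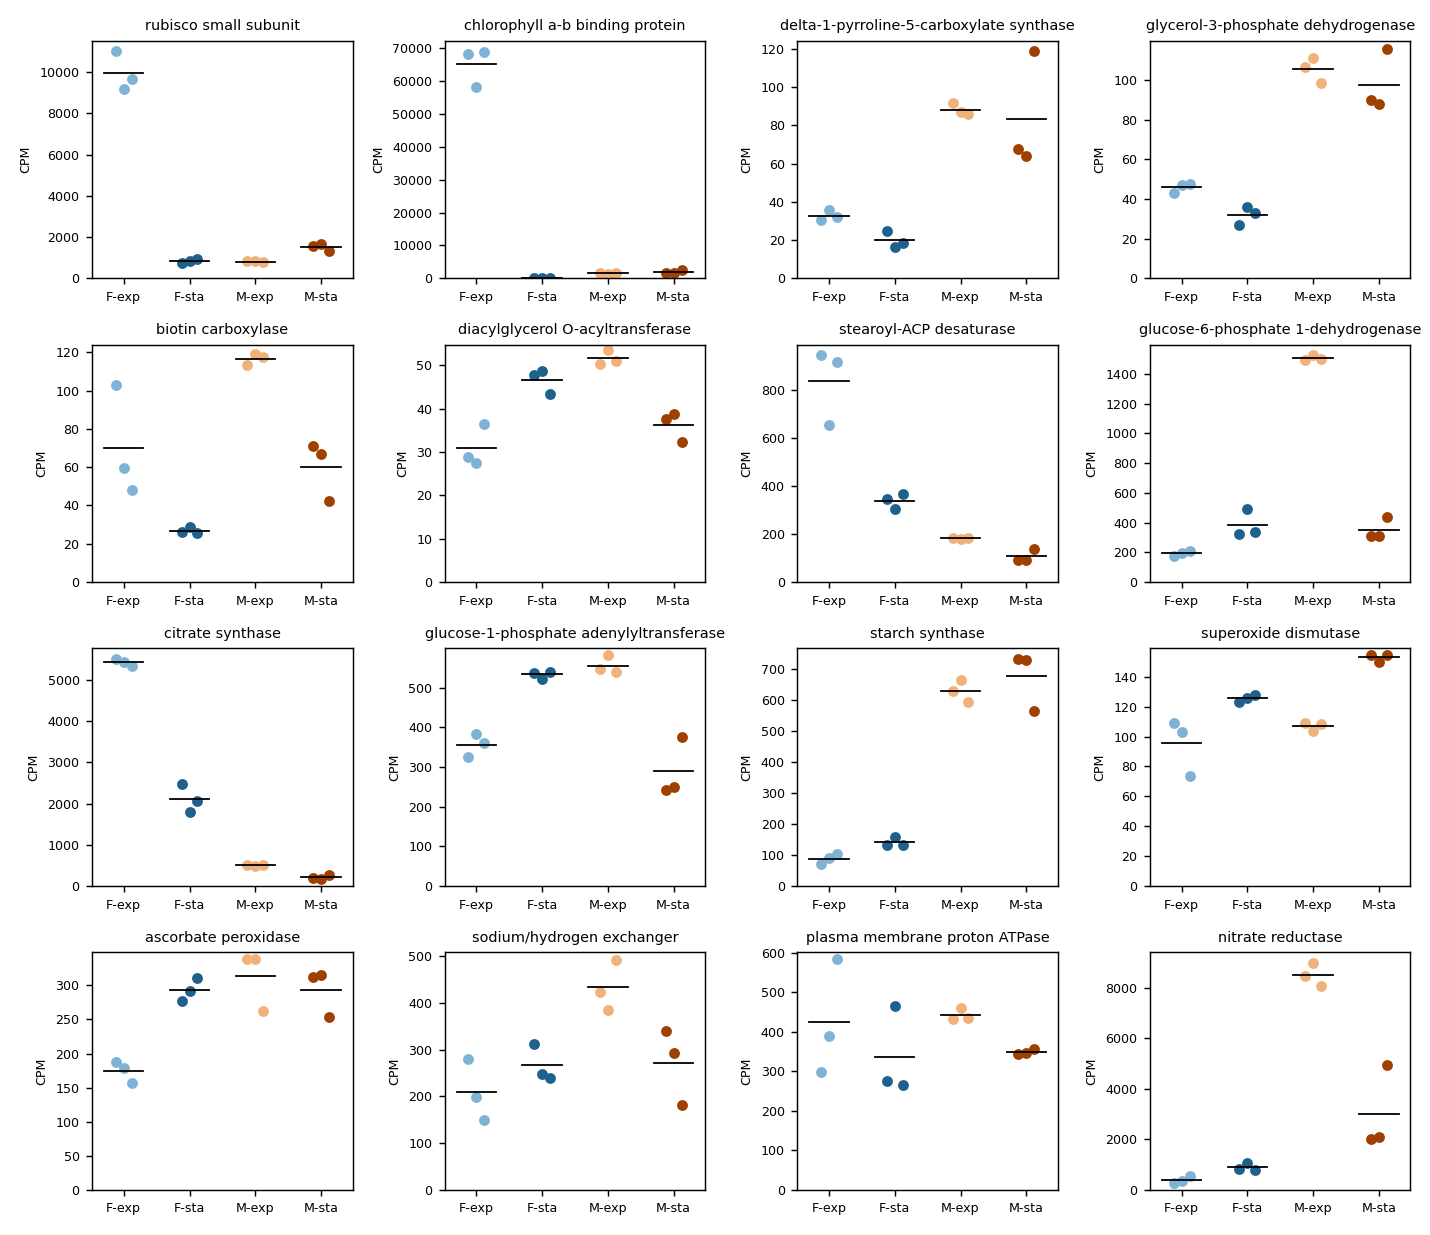
Levels in normalised CPM of the 16 panel genes with a tested match, with a point per library and a line at the group mean (F and M, freshwater and marine; exp and sta, exponential and stationary). The panel titled delta-1-pyrroline-5-carboxylate synthase shows the glutamate 5-kinase hit, and nitrate reductase stood at 8491 ± 447 CPM in marine exponential libraries.

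The authors' deposited table held 3565 higher and 4335 lower genes in marine medium at this phase, and 5872 of its calls were shared, all in the same direction. The table's fold changes lay a median of -0.107 from those here. The count was 886 by edgeR and 4442 by DESeq2 with shared-stem libraries summed, which leaves 1 marine exponential sample. From 6320 it fell to 3518, 3595, 3688 and 4102 without marine exponential replicates 1, 2 and 3 and freshwater exponential replicate 2.

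In stationary phase the salt comparison gave 2842 higher and 5451 lower genes. Nitrate reductase TRINITY_DN580_c1_g1 stood at 887 ± 146 CPM in freshwater and 3015 ± 1660 CPM in marine medium (log2 fold change 1.77 ± 0.37, FDR 0.00669), and granule-bound starch synthase 1 rose from 141 ± 13.5 to 675 ± 95.9 CPM. Citrate synthase was again lower, at 2103 ± 343 against 207 ± 44.6 CPM. Photosynthesis genes did not repeat the exponential pattern: the CP29 antenna protein (TRINITY_DN297_c0_g2) rose from 65.4 ± 11.2 to 392 ± 24.9 CPM and photosystem I subunit II (TRINITY_DN3598_c0_g1) from 56.7 ± 4.36 to 203 ± 25.2 CPM. Of the genes called lower 2978 were detected in freshwater only, and of those called higher 924 in marine only.

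Lists rich in freshwater-only genes were lower, but no list here kept its call with an estimated correlation. Cytosolic ribosomal proteins had 82 of 186 lower, 2 higher and 102 not called (87 and 2 adjusted over the list alone, median -1.23, adjusted p = 2.03e-16, and adjusted p = 0.225 with an estimated correlation). Flagella and basal body had 63 of 132 lower, 5 higher and 64 not called (89 and 8 adjusted over the list alone, median -7.44, or -4.78 at bounds, adjusted p = 4.48e-11, and adjusted p = 0.166 with an estimated correlation). Translation factors had 40 of 77 lower, 4 higher and 33 not called (45 and 4 adjusted over the list alone, median -0.90, or -1.02 at bounds, adjusted p = 2.18e-07, and adjusted p = 0.113 with an estimated correlation). The proteasome had 35 of 71 lower, 2 higher and 34 not called (39 and 3 adjusted over the list alone, median -5.15, or -2.54 at bounds, adjusted p = 4.59e-07, and adjusted p = 0.302 with an estimated correlation). In this order 80, 87, 33 and 36 of their members were detected in freshwater only, a set of undecided source with many animal hits. Over genes found in both media the medians were -0.19, -0.26, -0.25 and -0.18, and no call remained (adjusted p = 0.152, 0.193, 0.115 and 0.202).

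A smaller group of lists was lower too. Fatty acid degradation had 7 of 23 lower, 1 higher and 15 not called, also adjusted over the list alone (median -0.84, adjusted p = 0.00502, and adjusted p = 0.257 with an estimated correlation). Ion transport had 20 of 60 lower, 5 higher and 35 not called (28 and 10 adjusted over the list alone, median -0.68, or -0.73 at bounds, adjusted p = 0.00558, and adjusted p = 0.356 with an estimated correlation). DNA replication and cell cycle had 24 of 73 lower, 6 higher and 43 not called (28 and 7 adjusted over the list alone, median -0.69, or -0.70 at bounds, adjusted p = 0.00558, and adjusted p = 0.359 with an estimated correlation). Heat shock and chaperones had 25 of 70 lower, 11 higher and 34 not called (30 and 15 adjusted over the list alone, median -0.76, adjusted p = 0.0191, and adjusted p = 0.225 with an estimated correlation). For the respiratory chain the numbers were 22 of 74 lower, 5 higher and 47 not called (24 and 5 adjusted over the list alone, median -0.13, or -0.17 at bounds, adjusted p = 0.0145, and adjusted p = 0.354 with an estimated correlation). Over genes found in both media the medians of heat shock and the respiratory chain were 0.28 and 0.34 (adjusted p = 0.374 for both). Ion transport (median -0.16, adjusted p = 0.326) and fatty acid degradation (-0.47, 0.0511) lost their calls there too. DNA replication was called (-0.48, 0.0397, but adjusted p = 0.545 with an estimated correlation).

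Light harvesting was higher in 18 of 39 genes, lower in 3 and not called in 18 (19 and 3 adjusted over the list alone, median 1.34, adjusted p = 4.93e-06, and adjusted p = 0.257 with an estimated correlation). Its summed level was nonetheless alike, at 5726 ± 1485 CPM in freshwater and 5408 ± 975 CPM in marine medium, because 1 antenna gene (TRINITY_DN2252_c0_g1) stood at 3795 ± 1229 CPM in freshwater stationary and 1.35 ± 1.08 CPM in marine stationary libraries. Its near copy in the same assembly component, chlorophyll a-b binding protein 3, went the other way, from 125 ± 57.8 to 1799 ± 604 CPM, and the summed component changed by -0.86. Nitrogen assimilation had 15 of 26 higher, 5 lower and 6 not called (17 and 6 adjusted over the list alone, median 0.96, adjusted p = 0.00558, and adjusted p = 0.166 with an estimated correlation). Starch synthesis had 8 of 13 higher, 1 lower and 4 not called (9 and 1 adjusted over the list alone, median 0.67, adjusted p = 0.00502, and adjusted p = 0.257 with an estimated correlation). Chlorophyll biosynthesis had 14 of 35 higher, 5 lower and 16 not called (15 and 6 adjusted over the list alone, median 0.62, adjusted p = 0.0375, and adjusted p = 0.361 with an estimated correlation). Under the scaling matched to the authors' table the starch synthesis and chlorophyll biosynthesis calls were lost (adjusted p = 0.132 and 0.182). Bacterial cell markers had 5 of 9 higher, 0 lower and 4 not called (9 higher adjusted over the list alone, median 6.79, or 3.52 at bounds, adjusted p = 0.000549, and adjusted p = 0.113 with an estimated correlation). All 28 annotated members together reached 9.04 ± 2.97 CPM in freshwater and 69.3 ± 14.4 CPM in marine medium.

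**Figure D4:**
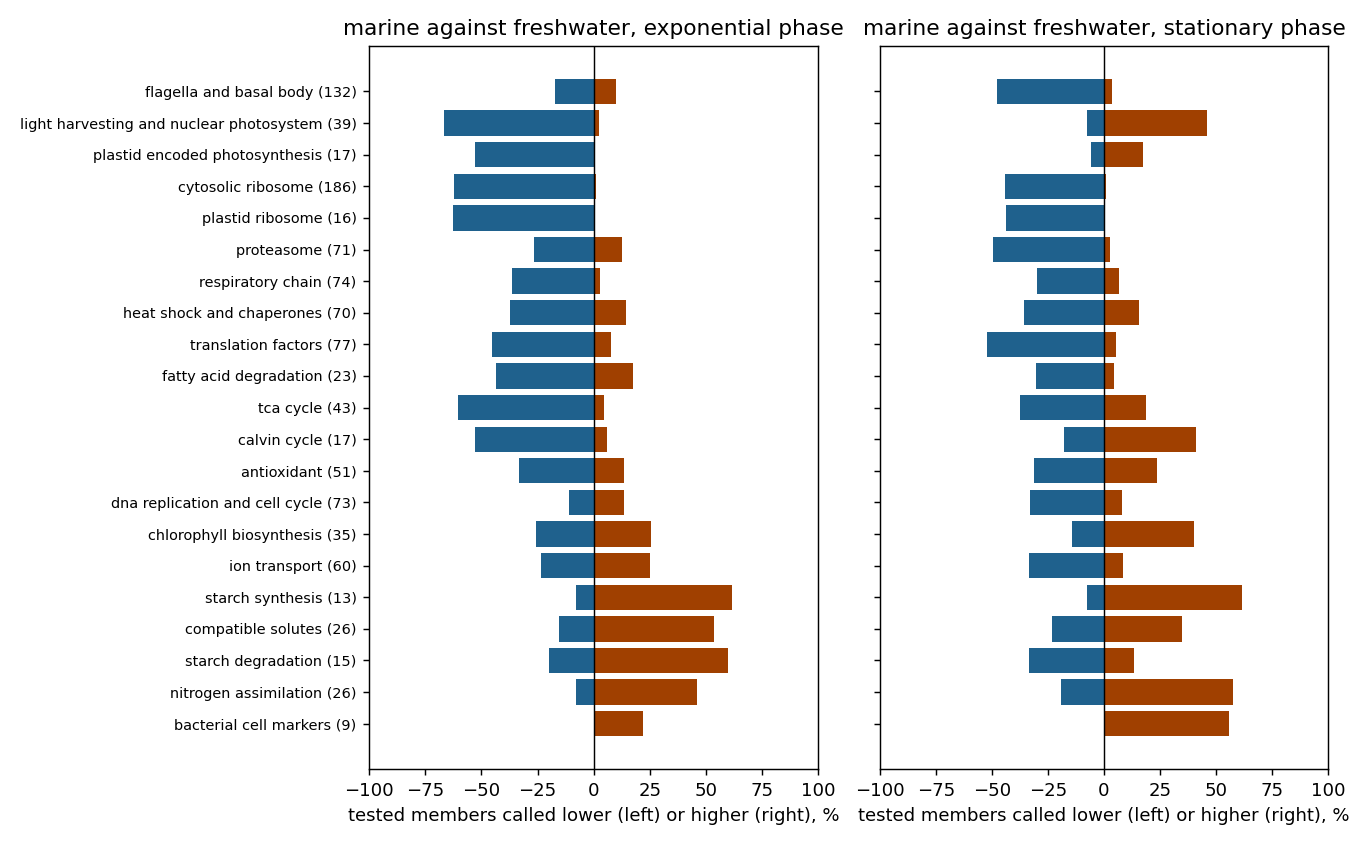
Share of each list's tested members, in percent, called lower in marine medium (bars to the left) or higher (bars to the right), in exponential and stationary phase, for lists called in either phase; the number tested follows the name. Light harvesting had 26 of 39 genes lower in exponential and 18 of 39 higher in stationary phase.

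The amine oxidase TRINITY_DN147_c0_g1 was again seen in marine medium only, at 935 ± 239 CPM and at least 8227-fold higher, and DUR3 changed by 7.87 ± 0.51 (FDR 4.82e-06), but their summed components changed by 2.54 and 1.84. A MICRORCHIDIA 2 hit (TRINITY_DN1371_c2_g1) had 1 count over the freshwater stationary group, a ratio of 3100 with a 95% exact counting interval of 556 to 122476. A terminal ear1 homolog (TRINITY_DN760_c0_g2) rose from 0.626 ± 0.208 to 68.0 ± 11.8 CPM and heat shock 70 kDa protein 14 (TRINITY_DN3212_c0_g3) from 0.668 ± 0.394 to 100 ± 87.6 CPM. At the other end stood freshwater-only genes, a peroxiredoxin (TRINITY_DN4964_c0_g1) at least 2589-fold lower and ribosomal proteins S21, S27, L39 (TRINITY_DN2601_c0_g2) and a plant-like L35a (TRINITY_DN49881_c0_g1) at least 1964-fold, 1744-fold, 1704-fold and 1548-fold lower. In the panel, the Rubisco small subunit was higher in marine medium (820 ± 97.5 against 1515 ± 170 CPM, FDR 0.00138), as were glutamate 5-kinase (19.8 ± 4.21 against 83.6 ± 30.9 CPM) and glycerol-3-phosphate dehydrogenase (31.9 ± 4.51 against 97.7 ± 15.3 CPM). Stearoyl-ACP desaturase was lower (339 ± 32.0 against 108 ± 26 CPM), and so was ADP-glucose pyrophosphorylase (533 ± 9.26 against 289 ± 74.8 CPM). Biotin carboxylase (26.7 ± 1.65 against 60 ± 15.7 CPM) was called with FDR 0.0124, a call lost without freshwater stationary replicate 1 or marine stationary replicates 1 or 2 (adjusted p up to 0.0654). Glucose-6-phosphate dehydrogenase (FDR 0.668), diacylglycerol acyltransferase (FDR 0.0774), superoxide dismutase (FDR 0.129), ascorbate peroxidase (FDR 0.994), the sodium/hydrogen exchanger (FDR 0.959) and the proton ATPase (FDR 0.917) were not called. With components summed, the terminal ear1 homolog, heat shock 70 kDa protein 14, L39 and the desaturase lost their calls, with log2 fold changes of 0.21, 0.13, -0.12 and -0.24 (adjusted p from 0.136 to 0.742). Diacylglycerol acyltransferase (-1.56, adjusted p = 0.000635) and superoxide dismutase (0.60, adjusted p = 0.0251) gained one.

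The authors' deposited table held 2314 higher and 6823 lower genes, and 6276 calls were shared in the same direction. Its scaling shifted the median fold change by -0.40 and the share of higher calls from 34.3% to 23.0%, while genes found in both media gave 1804 higher and 2291 lower, or 44.1% higher. Of 12 fits without 1 library, which tested more genes, 11 lost the nitrogen assimilation call (adjusted p up to 0.423). The respiratory chain call was lost in 10 (adjusted p up to 0.198). Without freshwater stationary replicate 3 the DNA replication (adjusted p = 0.18) and heat shock (adjusted p = 0.112) calls were lost, and without freshwater stationary replicate 2 that of fatty acid degradation (adjusted p = 0.1). The gene count fell to 3555 and 3574 without marine stationary replicates 1 and 2, and to 3786, 4412 and 4893 without freshwater stationary replicates 1, 2 and 3. It fell to 5175, 5236 and 5359 without marine exponential replicates 1, 2 and 3, to 5478 without freshwater exponential replicate 2, and was 1728 by edgeR and 7354 by DESeq2 with shared-stem libraries summed (2 marine stationary samples).

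Across the 31491 tested genes the salt fold changes of the 2 phases, which share no library, correlated with Pearson r = 0.578 and Spearman rho = 0.548; genes are not independent replicates, so no p is given. Called in both phases were 1272 genes as higher and 2458 as lower, where independent lists would share 264 and 587, and 289 went opposite ways. Over the 21521 genes detected in both media r was -0.0267 and rho 0.171, with 254 opposite calls, 944 shared higher and 1122 shared lower, where independent lists would share 206 and 221. A limit on counts in both media removes genes with a large salt effect of 1 sign in both phases, so the fall of r was largely built in. Shared calls stayed above those numbers.

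The passage from exponential to stationary phase in freshwater gave 2033 higher and 1392 lower genes. Antenna genes fell. Chlorophyll a-b binding protein 215 (TRINITY_DN10362_c0_g1) went from 19585 ± 2014 to 30.6 ± 17.3 CPM, protein 3 from 65219 ± 5937 to 125 ± 57.8 CPM and the LHCII type I gene TRINITY_DN546_c0_g2 from 6434 ± 364 to 13.5 ± 8.58 CPM. The Rubisco small subunit fell from 9946 ± 948 to 820 ± 97.5 CPM and citrate synthase from 5428 ± 81.0 to 2103 ± 343 CPM. A further 2 members of antenna components rose, TRINITY_DN2252_c0_g1 from 1.87 ± 0.528 to 3795 ± 1229 CPM and TRINITY_DN546_c0_g9 from 0.185 ± 0.0892 to 223 ± 103 CPM, but the summed components, which hold protein 3 and TRINITY_DN546_c0_g2, changed by -4.33 and -3.59.

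Light harvesting had 29 of 39 lower, 2 higher and 8 not called, also adjusted over the list alone (median -4.58, or -4.85 at bounds, adjusted p = 1.45e-39). The Calvin cycle had 10 of 17 lower, 1 higher and 6 not called (11 and 2 adjusted over the list alone, median -1.49, adjusted p = 3.16e-11). These 2 lists kept their calls with an estimated correlation (adjusted p = 0.00582 and 0.0387). Plastid ribosomal proteins had 8 of 16 lower, 0 higher and 8 not called (8 and 1 adjusted over the list alone, median -1.31, adjusted p = 6.16e-08, and adjusted p = 0.186 with an estimated correlation). The tricarboxylic acid cycle had 16 of 43 lower, 3 higher and 24 not called (16 and 4 adjusted over the list alone, median 0, or -0.53 at bounds, adjusted p = 2.19e-07, and adjusted p = 0.0736 with an estimated correlation). Plastid-encoded photosynthesis had 3 of 17 lower, 0 higher and 14 not called (6 adjusted over the list alone, median -1.73, or -1.60 at bounds, adjusted p = 2.11e-06, and adjusted p = 0.186 with an estimated correlation). Without the nuclear iron-sulfur subunit genes the median was -1.60 (adjusted p = 2.86e-05).

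Pigment, lipid and glycolysis lists were lower as well. Fatty acid synthesis had 10 of 23 lower, 0 higher and 13 not called, also adjusted over the list alone (median -0.26, or -0.68 at bounds, adjusted p = 7.82e-05, and adjusted p = 0.164 with an estimated correlation). Chlorophyll biosynthesis had 12 of 35 lower, 1 higher and 22 not called (15 and 3 adjusted over the list alone, median -0.39, or -0.52 at bounds, mean 0.00455, adjusted p = 0.000476, and adjusted p = 0.203 with an estimated correlation). Carotenoid biosynthesis had 2 of 13 lower, 1 higher and 10 not called (4 and 1 adjusted over the list alone, median -0.44, or -0.51 at bounds, adjusted p = 0.0139, and adjusted p = 0.135 with an estimated correlation). Glycolysis and pyruvate metabolism had 16 of 63 lower, 5 higher and 42 not called (20 and 9 adjusted over the list alone; adjusted p = 0.00937, and adjusted p = 0.253 with an estimated correlation), although its median (0.13) and mean (0.28) were above 0. The respiratory chain had 12 of 74 lower, 4 higher and 58 not called (15 and 7 adjusted over the list alone, median 0.13, mean -0.39, adjusted p = 0.025, and adjusted p = 0.276 with an estimated correlation). Cytosolic ribosomal proteins had 11 of 186 lower, 1 higher and 174 not called (5 and 1 adjusted over the list alone, median -0.13, adjusted p = 0.0463, and adjusted p = 0.684 with an estimated correlation). Under the scaling matched to the authors' table the calls of these last 3 lists were lost (adjusted p = 0.0567, 0.0567 and 0.24).

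Higher in stationary phase were flagella and basal body genes, with 14 of 132 higher, 2 lower and 116 not called (27 and 2 adjusted over the list alone, median 1.87, or 1.89 at bounds, adjusted p = 8.11e-08, and adjusted p = 0.203 with an estimated correlation). Of the 132 genes 87 were freshwater only, and over the 42 found in both media the median was 0.38 (adjusted p = 0.00523, and adjusted p = 0.179 with an estimated correlation). The proteasome had 17 of 71 higher, 0 lower and 54 not called (19 adjusted over the list alone, median 0.74, adjusted p = 6.16e-06, and adjusted p = 0.268 with an estimated correlation). An endoglucanase (TRINITY_DN575_c0_g2) rose from 26.8 ± 7.24 to 604 ± 56.7 CPM. A proton/sulfate cotransporter (TRINITY_DN3998_c0_g2) had 1 count over the freshwater exponential group and 69.3 ± 78.5 CPM in stationary libraries, a ratio of 1620 with a 95% exact counting interval of 290 to 64033. Another sulfate cotransporter (TRINITY_DN943_c1_g1; 6.32 ± 10.6 to 254 ± 170 CPM) lost its call without any 1 of 11 libraries (adjusted p up to 0.126), and its summed component changed by 1.2. Chlorophyll a-b binding genes TRINITY_DN1819_c0_g2 (4553 ± 169 to 11.5 ± 6.76 CPM) and TRINITY_DN546_c0_g10 (1078 ± 261 to 5.17 ± 1.85 CPM) fell too.

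In the panel, stearoyl-ACP desaturase (FDR 0.00107) and biotin carboxylase (FDR 0.00789) fell in freshwater, and glucose-6-phosphate dehydrogenase stood higher (FDR 0.00597), a call lost without freshwater exponential replicate 1, 2 or 3 (adjusted p up to 0.0935). Calls of ascorbate peroxidase, granule-bound starch synthase, ADP-glucose pyrophosphorylase, diacylglycerol acyltransferase and glycerol-3-phosphate dehydrogenase were each lost without any 1 of 8, 8, 9, 11 and 3 libraries (adjusted p up to 0.211, 0.334, 0.334, 0.409 and 0.185). Nitrate reductase (FDR 0.06), glutamate 5-kinase (FDR 0.076), superoxide dismutase (FDR 0.0811), the sodium/hydrogen exchanger (FDR 0.417) and the proton ATPase (FDR 0.411) were not called. With components summed, ascorbate peroxidase, both starch genes and glucose-6-phosphate dehydrogenase lost theirs (adjusted p from 0.0823 to 0.213), while glutamate 5-kinase (-1.06, adjusted p = 0.00582) and superoxide dismutase (-0.996, adjusted p = 0.00317) were called lower. Upper-quartile scaling shifted the median by -0.29 and gave 1310 higher and 1895 lower genes, or 40.9% higher instead of 59.4%, and the authors' scaling shifted it by 0.14. Lower genes also outnumbered higher ones with components summed (1071 higher, 1486 lower), with Viridiplantae hits only (735 and 801), at a mean of at least 50 counts (1798 and 1877) and with shared-stem libraries summed (341 and 546 by edgeR, but 2987 and 2009 by DESeq2). The same held without any 1 of the 6 exponential libraries or freshwater stationary replicates 2 or 3 (39.9% to 43.6% higher). The count of 3425 fell to 2151, 2256, 2195 and 2246 without freshwater exponential replicates 1 and 2 and freshwater stationary replicates 1 and 2, and was 5883 with DESeq2's own test.

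In marine medium the same passage changed few genes, 98 higher and 416 lower. The plastid-encoded Rubisco large chain rose from 1.38 ± 0.393 to 10.1 ± 2.94 CPM, a call lost with its component summed (log2 fold change 0.35 instead of 2.86, adjusted p = 0.378). Citrate synthase fell from 503 ± 17.8 to 207 ± 44.6 CPM and glucose-6-phosphate dehydrogenase from 1509 ± 19.3 to 353 ± 75.3 CPM. The enzyme 15-cis-zeta-carotene isomerase (TRINITY_DN2412_c0_g1), of carotenoid synthesis, fell from 89.3 ± 2.74 to 12.1 ± 7.08 CPM. In each of the 12 lists called here most members were not called.

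Plastid-encoded photosynthesis had 5 of 17 higher, 0 lower and 12 not called (9 adjusted over the list alone, median 2.87, adjusted p = 4.87e-10, and adjusted p = 0.121 with an estimated correlation). Light harvesting had 1 of 39 higher, 0 lower and 38 not called (14 adjusted over the list alone, median 0.50, adjusted p = 6.08e-05, and adjusted p = 0.269 with an estimated correlation), a call lost under upper-quartile scaling (adjusted p = 0.127). Photosystem II protein D1 (TRINITY_DN51627_c0_g1) stood at 6.41 ± 1.26 and 54.0 ± 44.4 CPM and lost its call without any 1 marine exponential library (adjusted p up to 0.121). Bacterial cell markers had 0 of 9 called (2 higher adjusted over the list alone, median 2.64, adjusted p = 0.00745, and adjusted p = 0.121 with an estimated correlation). Starch degradation had 4 of 15 lower, 0 higher and 11 not called (7 adjusted over the list alone, median -0.29, or -0.32 at bounds, adjusted p = 1.18e-06) and kept its call with an estimated correlation (adjusted p = 0.0411). In it the glucanotransferase DPE1 (TRINITY_DN6732_c0_g2) fell from 44.3 ± 1.16 to 13.3 ± 2.38 CPM.

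A further 8 lists were called lower with no member higher. Ion transport had 3 of 60 lower (6 adjusted over the list alone, median -0.02, or -0.34 at bounds, adjusted p = 1.64e-05, and adjusted p = 0.138 with an estimated correlation). DNA replication and cell cycle had 5 of 73 lower (11 adjusted over the list alone, median -0.14, or -0.27 at bounds, adjusted p = 5.96e-05, and adjusted p = 0.17 with an estimated correlation). Glycolysis had 5 of 63 lower (6 adjusted over the list alone, median -0.00386, or -0.13 at bounds, adjusted p = 0.000109, and adjusted p = 0.126 with an estimated correlation). Fatty acid synthesis had 3 of 23 lower (8 adjusted over the list alone, median -0.12, or -0.52 at bounds, adjusted p = 0.000337, and adjusted p = 0.126 with an estimated correlation). Among compatible solute genes 1 of 26 was lower (2 adjusted over the list alone, median -0.14, or -0.22 at bounds, adjusted p = 0.000337, and adjusted p = 0.126 with an estimated correlation). Translation factors had 1 of 77 lower (2 adjusted over the list alone, median 0, or -0.34 at bounds, adjusted p = 0.00113, and adjusted p = 0.126 with an estimated correlation). In the autophagy list 1 of 15 was lower (2 adjusted over the list alone, median -0.21, or -0.24 at bounds, adjusted p = 0.00113, and adjusted p = 0.121 with an estimated correlation). In starch synthesis 2 of 13 were lower (5 adjusted over the list alone, median -0.21, adjusted p = 0.00745, and adjusted p = 0.205 with an estimated correlation). Starch synthesis lost its call without any 1 of 8 libraries (adjusted p up to 0.144) with DESeq2 size factors (adjusted p = 0.0771) and over genes of both media (0.0863).

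Chitin synthase 2 (TRINITY_DN6745_c0_g1; 36.0 ± 0.324 to 0.539 ± 0.347 CPM), cyclin-dependent kinase B1-1 (TRINITY_DN5338_c0_g1; 25 ± 2.92 to 0.987 ± 0.232 CPM) and the plastid division dynamin ARC5 (TRINITY_DN6195_c0_g1; 15.9 ± 1.61 to 0.969 ± 0.0516 CPM) were among the lowest fold changes. They lost their calls without any 1 of 2, 10 and 5 libraries (adjusted p up to 0.0705, 0.189 and 0.0863). A drkA-like kinase (TRINITY_DN1130_c0_g4; 2.32 ± 1.13 to 0.273 ± 0.120 CPM) had no change once its assembly component was summed (0.02 on the log2 scale). The highest fold changes included an intron-encoded endonuclease (TRINITY_DN2077_c0_g3; 50 ± 1.33 to 698 ± 466 CPM) and the terminal ear1 homolog (8.20 ± 3.52 to 68.0 ± 11.8 CPM), whose summed component changed by 0.09. In the panel the Rubisco small subunit (805 ± 31.7 to 1515 ± 170 CPM, FDR 0.0127) and ADP-glucose pyrophosphorylase (556 ± 22.7 to 289 ± 74.8 CPM, FDR 0.0177) lost their calls without any 1 of 3 and 5 libraries (adjusted p up to 0.078 and 0.117). The remaining 12 products were not called, with nitrate reductase at FDR 0.0817.

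The count in marine medium was unsteady. It ran from 329 to 1745 over scalings, with 106 higher and 1639 lower under upper-quartile factors (median shift -0.36, 6.07% higher instead of 19.1%), was 1723 with DESeq2's own test (839 higher, 884 lower) and 1027 without marine stationary replicate 3. It was 82, 87 and 103 without marine exponential replicates 1, 2 and 3, 114 and 129 without marine stationary replicates 1 and 2, and between 200 and 316 without freshwater exponential replicates 1, 2 or 3 or freshwater stationary replicates 1 or 3. With shared-stem libraries summed, 1 marine exponential sample stands against 2 marine stationary ones. There edgeR called 0 genes (1254 at an unadjusted p under 0.05) and DESeq2 1048 (730 higher, 318 lower), which this arm of 1 sample cannot decide. Phase fold changes in the 2 media correlated across genes with r = 0.0444 and rho = 0.0248, with 24 shared higher, 105 shared lower and 104 opposite calls where independent lists would share 6.33 and 18.4.

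The test of the difference between the salt effects of the 2 phases called 751 genes higher and 1507 lower, higher meaning a larger marine to freshwater ratio in stationary phase. Antenna genes high in freshwater exponential libraries only had positive values, such as TRINITY_DN546_c0_g2 (11.28 ± 0.92, or 3.69 for its summed component) and chlorophyll a-b binding protein 215 (10.15 ± 0.78). The Rubisco small subunit had a value of 4.51 ± 0.21, and glucose-6-phosphate dehydrogenase, high in marine exponential libraries, one of -3.08 ± 0.27. Starch-mobilising glucanotransferase DPE1 stood at -3.19 ± 0.23.

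Light harvesting had 28 of 39 higher, 2 lower and 9 not called (29 and 2 adjusted over the list alone, median 5.17, or 4.83 at bounds, adjusted p = 3.38e-45, and adjusted p = 0.00627 with an estimated correlation). Plastid-encoded photosynthesis had 10 of 17 higher, 0 lower and 7 not called (13 adjusted over the list alone, median 4.25, or 4.02 at bounds, adjusted p = 2.13e-15, and adjusted p = 0.0558 with an estimated correlation). Of the plastid ribosomal proteins 7 of 16 were higher, 0 lower and 9 not called (10 and 1 adjusted over the list alone, median 1.46, adjusted p = 1.05e-09, and adjusted p = 0.147 with an estimated correlation). The Calvin cycle had 8 of 17 higher, 1 lower and 8 not called (10 and 2 adjusted over the list alone, median 1.16, adjusted p = 2.35e-07, and adjusted p = 0.0558 with an estimated correlation). The tricarboxylic acid cycle had 14 of 43 higher, 2 lower and 27 not called (14 and 3 adjusted over the list alone, median 0.67, adjusted p = 2.14e-06, and adjusted p = 0.0558 with an estimated correlation). Starch degradation had 7 of 15 lower, 1 higher and 7 not called (8 and 1 adjusted over the list alone, median -0.94, adjusted p = 9.33e-06) and kept its call with an estimated correlation (adjusted p = 0.0482).

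Chlorophyll biosynthesis had 6 of 35 higher, 1 lower and 28 not called (7 and 1 adjusted over the list alone, median 0.78, adjusted p = 0.000585, and adjusted p = 0.22 with an estimated correlation). Cytosolic ribosomal proteins had 4 of 186 higher, 0 lower and 182 not called (0 adjusted over the list alone, median 0.17, or 0.13 at bounds, adjusted p = 7.41e-05, and adjusted p = 0.454 with an estimated correlation). The respiratory chain had 9 of 74 higher, 5 lower and 60 not called (10 and 5 adjusted over the list alone, median 0.58, or 0.43 at bounds, adjusted p = 0.00284, and adjusted p = 0.22 with an estimated correlation). The proteasome had 6 of 71 lower, 0 higher and 65 not called (12 adjusted over the list alone, median -0.95, or -0.87 at bounds, adjusted p = 0.000585, and adjusted p = 0.454 with an estimated correlation). That call was lost without freshwater exponential replicate 3, freshwater stationary replicate 3 or marine exponential replicates 1 or 3 (adjusted p up to 0.119). Ion transport had 10 of 60 lower, 2 higher and 48 not called (17 and 2 adjusted over the list alone, median -0.93, or -0.95 at bounds, adjusted p = 0.00347, and adjusted p = 0.336 with an estimated correlation). That call was lost without freshwater exponential replicates 1 or 2, freshwater stationary replicate 2 or any 1 marine exponential library (adjusted p up to 0.125). Of the flagella genes 11 of 132 were lower, 0 higher and 121 not called, also adjusted over the list alone (median -1.87, or -2.01 at bounds, adjusted p = 0.0211, and adjusted p = 0.493 with an estimated correlation). It was lost without marine stationary replicate 3 (adjusted p = 0.0845). Fatty acid synthesis had 2 of 23 higher, 0 lower and 21 not called (4 adjusted over the list alone, median 0.55, adjusted p = 0.0085, and adjusted p = 0.247 with an estimated correlation). It was lost without freshwater stationary replicate 1 (adjusted p = 0.0626). Autophagy had 3 of 15 lower (4 adjusted over the list alone, median -0.97, or -1.06 at bounds, adjusted p = 0.0443, and adjusted p = 0.22 with an estimated correlation). DNA replication had 7 of 73 lower and 1 higher, also adjusted over the list alone (median -0.41, or -0.32 at bounds, adjusted p = 0.0446, and adjusted p = 0.493 with an estimated correlation). The autophagy and DNA replication calls were lost without any 1 of 10 and 11 libraries, with DESeq2 size factors (adjusted p = 0.146 and 0.191) and over genes of both media (0.152 and 0.12).

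The authors' deposited table gave 1106 higher and 3280 lower genes for this difference, with 2127 shared calls in the same direction. Against 33.3% here, higher calls made up 45.8% with DESeq2 size factors (944 higher, 1118 lower; median shift 0.18) and 19.1% under the authors' scaling (538 higher, 2275 lower; median shift -0.30). The count was 4279 with DESeq2's own test. With shared-stem libraries summed, and so 1 marine exponential sample, it was 55 by edgeR (34 higher, 21 lower) and 2355 by DESeq2. Higher calls became the majority with components summed (894 higher, 682 lower), with Viridiplantae hits only (645 and 546), and without freshwater exponential replicate 3, freshwater stationary replicates 2 or 3 or any 1 marine exponential library (50.6% to 57.0% higher). The count fell to 981, 987 and 1058 without marine exponential replicates 1, 2 and 3, to 1170 and 1216 without marine stationary replicates 1 and 2, to 1361 and 1389 without freshwater exponential replicates 1 and 2, and to 1459 and 1435 without freshwater stationary replicates 2 and 3.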

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

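The results in this part came from the planned test of a difference between the salt effects of the 2 phases. Of the tests of explanations, those of scaling and of shared reads were chosen after the result was seen, and that on Viridiplantae hits was written before.

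The difference between the salt effects passed the test in 2258 genes. Among lists, median differences were 5.17 for light harvesting, 4.25 for plastid-encoded photosynthesis, 1.46 for plastid ribosomes, 1.16 for the Calvin cycle, 0.665 for the tricarboxylic acid cycle, 0.778 for chlorophyll biosynthesis, 0.577 for the respiratory chain, 0.549 for fatty acid synthesis and 0.165 for cytosolic ribosomes. They were -0.944 for starch degradation, -0.952 for the proteasome, -0.925 for ion transport, -1.87 for flagella, -0.965 for autophagy and -0.407 for DNA replication. With an estimated correlation, light harvesting (adjusted p = 0.00627) and starch degradation (adjusted p = 0.0482) kept their calls.

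Antenna genes stood out. TRINITY_DN546_c0_g2 had a difference of 11.28, chlorophyll a-b binding protein 215 (TRINITY_DN10362_c0_g1) one of 10.15, a type 2 protein (TRINITY_DN2252_c0_g4) one of 9.81, chlorophyll a-b binding protein 3 (TRINITY_DN2252_c0_g2) one of 9.34 and TRINITY_DN1819_c0_g2 one of 8.79. CP29 (TRINITY_DN297_c0_g2) followed at 5.88 and photosystem I subunit II (TRINITY_DN3598_c0_g1) at 5.03. The Rubisco small subunit (TRINITY_DN1599_c0_g1) stood at 4.51, the Rubisco large chain (TRINITY_DN1417_c0_g4) at 3.655 and the nuclear-encoded cytochrome b6-f iron-sulfur subunit (TRINITY_DN123_c0_g2) at 1.825. The call of the large chain was lost with its assembly component summed (0.24, adjusted p = 0.617), and the component of the type 2 protein and protein 3 had 4.85. Plastid ribosomal proteins L3-1 (TRINITY_DN6489_c0_g2) and L17 (TRINITY_DN5342_c0_g2) had 1.685 and 1.525.

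Negative differences were found for the antenna genes TRINITY_DN2252_c0_g1 (-12) and TRINITY_DN546_c0_g9 (-10.36), whose summed components had positive ones of 4.85 and 3.69. A proton/sulfate cotransporter (TRINITY_DN3998_c0_g2) stood at a fitted -11.22, which rests on 1, 4 and 2 counts in 3 of the 4 groups. Its marine to freshwater ratio was 2.38 in exponential phase (95% exact counting interval 0.236 to 117), and its freshwater to marine ratio 1523 in stationary phase (421 to 12586). Negative values also came from an endoglucanase (TRINITY_DN575_c0_g2; -4.92) and a TAO1 hit (TRINITY_DN2510_c0_g2; -4.53). In the panel the values were -3.08 for glucose-6-phosphate dehydrogenase (TRINITY_DN769_c0_g1), -2.70 for nitrate reductase (TRINITY_DN580_c1_g1), -1.52 for ADP-glucose pyrophosphorylase (TRINITY_DN86_c0_g1), -1.10 for diacylglycerol acyltransferase (TRINITY_DN290_c3_g2) and -0.84 for ascorbate peroxidase (TRINITY_DN247_c0_g1). Calls were lost without any 1 of 2 libraries for nitrate reductase (adjusted p up to 0.0534), of 9 for diacylglycerol acyltransferase (up to 0.288) and of 10 for ascorbate peroxidase (up to 0.555), the last also with its component summed (0.288).

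The pattern weighed here is light harvesting, lower in marine medium in exponential but not in stationary phase. Scaling as the cause is argued against, since the list's median difference ran from 4.97 to 5.33 under 3 other scalings. Reads moving between near copies are also argued against, because the summed share of counts in the lowest freshwater exponential library was 12.7 times that of the highest other library. Dilution by another organism is argued against by a median of 5.33 over genes with a Viridiplantae hit. An effect of medium and phase on the alga may therefore underlie it and stays a hypothesis, as the hour of harvest and the light regime are not given and were not tested.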

How the results depend on the processing

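The fit on genes detected in both media, the sums over assembly components, and list tests under DESeq2 size factors and the authors' scaling were chosen after the data were seen. Values follow the order salt exponential, salt stationary, phase freshwater, phase marine and difference of salt effects, unless named. The cause of a change was not tested. Fits without a library tested more genes (37962 to 41585), as did summed stems (51469).

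Gene counts of 6320, 8293, 3425, 514 and 2258 became 3461, 3420, 1912, 130 and 1101 at an FDR under 0.01, 4010, 4069, 2221, 257 and 1402 without a filter, and 2058, 2049, 1536, 297 and 1191 with Viridiplantae hits only, where fewer genes were tested. Shared-stem libraries summed leave 9 samples, 1 of them marine exponential and 2 marine stationary. On these edgeR called 886, 1728, 887, 0 and 55 (for the 0, 1254 had an unadjusted p under 0.05) and DESeq2 4442, 7354, 4996, 1048 and 2355. In the salt stationary comparison a mean of at least 50 counts gave 4784 and genes of both media 4095. DESeq2's own test gave 5883, 1723 and 4279 in the last 3 comparisons. The marine phase count was also 324 with a 2-fold minimum, 329 with DESeq2 size factors, 1745 with upper-quartile factors, 982 under the authors' scaling and 302 with components summed.

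The replicate block, which takes replicate numbers as pairing, gave 4143 and 3973 for the salt comparisons. The numbers do not pair the samples, as correlations of same-numbered differences ran from -0.129 to 0.0847.

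Leaving out 1 library at a time gave 3518 to 6309, 3555 to 6017, 2151 to 3669, 82 to 1027 and 981 to 2853 genes. The lowest counts came without marine exponential replicate 1, marine stationary replicate 1, freshwater exponential replicate 1, and marine exponential replicate 1 for the last 2. The highest all came without marine stationary replicate 3. Called lists ran from 17 to 21, 10 to 14, 13 to 19, 11 to 13 and 12 to 18. Agreement of salt effects ran from 0.467 to 0.518 and of phase effects from -0.0183 to 0.0113.

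Called lists numbered 17, 14, 13, 12 and 15, and 6, 0, 2, 1 and 2 with an estimated correlation in camera (for the 0, fry called 24). Fry called 24 in salt stationary and 21 in phase freshwater. With Viridiplantae hits only 10, 8, 8, 6 and 8 were called, and 8 in salt stationary over both media. Summed stems gave 22 in phase freshwater and 6 in phase marine, and upper-quartile factors 19 in phase marine.

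The direction of the test changed for some lists, given with the median under that setting, which need not change sign. In salt exponential, flagella had -0.568 with Viridiplantae hits and 0.339 over both media, the proteasome -0.0525 and 0.289, and phosphate uptake, not called by camera, -1.41 in fry. In salt stationary, heat shock had -0.0939 and 0.276, the respiratory chain 0.451 with Viridiplantae hits and carotenoid biosynthesis 0.151 in fry. In phase marine with Viridiplantae hits, cytosolic ribosomes had 0.151 and the respiratory chain 0. DNA replication in the difference ran from -0.344 without marine stationary replicate 2 to 0.249 without freshwater stationary replicate 3, and its test changed direction without freshwater exponential replicate 3 too (median -0.0202).

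Of 179 called results of named genes, 24 lost their call with assembly components summed, 8 changed direction and 17 more kept a call with a log2 fold change under 0.5 times the original. Genes whose summed component went the other way were TRINITY_DN1132_c0_g1 (-0.996 in phase freshwater, -0.881 in salt exponential), TRINITY_DN2252_c0_g1 (-4.33 in phase freshwater, 4.85 in the difference), TRINITY_DN546_c0_g9 (-3.59 and 3.69), TRINITY_DN1130_c0_g4 (0.0203 in phase marine, and 0.138 summed by entry), TRINITY_DN139_c0_g2 (-0.765) and TRINITY_DN290_c3_g2 (-0.174) in salt exponential, and TRINITY_DN2252_c0_g2 (-0.864) in salt stationary. In the difference, TRINITY_DN1132_c0_g1 (1.49), TRINITY_DN3484_c0_g1 (1.08) and TRINITY_DN986_c0_g1 (1.27) gained a call. The authors' scaling gave TRINITY_DN247_c0_g1 -0.4 in salt stationary.

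Agreement of salt effects was 0.578, and 0.418 without a filter, 0.385 at a mean of at least 50 counts, 0.42 with stems summed and -0.0267 over both media, a limit that lowers r by construction. Agreement of phase effects was 0.0444, and -0.0389, -0.0295 and 0.0851 without a filter, with stems summed and over both media. A sign change of r counted only beyond 2 jackknife standard errors, a rule set after these values were seen. Viridiplantae shares at an E-value of at most 1e-50 were 24, 21.6, 27.9 and 23.9% (freshwater exponential and stationary, marine exponential and stationary) and bacterial shares 1.3, 1.1, 0.81 and 0.652%. As shares of expressed genes they were 18.1, 15.3, 14.5 and 12.5%, and 2.31, 2.07, 1.86 and 1.88%.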

Other observations

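The oxidative pentose phosphate list summed to 669 ± 51 CPM (n = 3) in freshwater exponential and 2033 ± 25.5 CPM in marine exponential libraries, of which 1 glucose-6-phosphate dehydrogenase gene held 1509 CPM, and was not called (2 of 6 genes higher, 0 lower, adjusted p = 0.231). Phosphate uptake summed to 1063 ± 179 and 1996 ± 116 CPM in freshwater exponential and stationary libraries, with 5 of 21 genes higher, 1 lower and an adjusted p = 0.125. Glycerolipid assembly had 6 of 16 genes higher and 1 lower with salt in exponential phase (adjusted p = 0.303), histones 3 of 14 higher and 2 lower (adjusted p = 0.981), and DNA repair and photoprotection 1 of 5 higher and 1 lower (adjusted p = 0.891). Those 5 lists were called in none of the 5 comparisons by camera over all tested genes.

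The animal and fungal marker lists were too small to test. Animal markers summed to 50.2 ± 69.6, 9.76 ± 9.94, 1.97 ± 0.767 and 1.55 ± 0.725 CPM in freshwater exponential, freshwater stationary, marine exponential and marine stationary libraries. The 2 fungal marker genes summed to 262 ± 17.1, 109 ± 10.2, 519 ± 17.5 and 252 ± 64.6 CPM.

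Of the tests that follow, these were chosen after the values were seen: the sets of ribosomal proteins, the alga's own genes in 1 medium, and both tests of shared-stem libraries. The lineage of ribosomal hits, near copies, and the splits of samples were written before.

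Genes detected in freshwater only included 84 of 209 cytosolic ribosomal protein genes and 278 of 354 flagella genes, but 1 of 42 light-harvesting genes. Near copies made by the assembly stay open, as copies can differ in entry. Of freshwater-only genes with a hit 16.8% shared theirs with a gene of both media. Genes of the alga expressed in 1 medium are argued against as the whole set, since 23.0% of their hits were from Viridiplantae, against 55.6% of hits of genes in both media. The test of another eukaryote written beforehand did not favour it: the Viridiplantae share of ribosomal hits was -9.72 points apart, inside the 10 points written as speaking against it (27.4% against 37.1%, Fisher exact p = 0.177), but its interval of -22.5 to 3.06 left it undecided once the whole interval was required, a requirement added after the value was seen. In a later test 93.8% of ribosomal products of both media (60 of 64) also had a freshwater-only gene. By exact product name, another measure, it held for 17 of 33 proteasome, 23 of 43 translation factor and 12 of 52 DNA replication products. Another eukaryote in freshwater cultures may be a source, which these values leave undecided.

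Libraries with shared code stems lay closer together. Marine stationary pairs without a shared stem differed by at least 0.691, above the freshwater range of 0.345 to 0.564, and 4.83 times as much as the pair with a shared stem. Both of those pairs hold marine stationary replicate 3, so 1 library decides these values. A shared culture or library preparation and less variation between cultures in marine medium cannot be told apart. The labels name biological replicates.

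Other splits of the 6 libraries of a comparison number 10 with the real 1, too few for a share under 0.05. In each of the 4 pairwise comparisons 1 of 10 splits, the real one, gave as many genes. Real and highest other gene counts were 6320 and 1 (salt, exponential), 8293 and 0 (salt, stationary, by edgeR, with 12769 genes at an unadjusted p under 0.05 and 9400 by DESeq2 in the real split), 3425 and 3 (phase, freshwater), and 514 and 1 (phase, marine). For lists they were 17 and 12, 14 and 9, 13 and 9, and 12 and 4, again with 1 of 10 splits as large. For the difference of salt effects, 2 of 100 splits drawn, 1 of them real, gave 2258 genes or more. The other (12720 genes) swapped media within 1 phase and measured the average salt effect. The rest mixed media within groups, where the salt effect adds spread, so this share cannot exclude chance. Shared-stem libraries may not be independent. For the 15 lists 6 of 100 gave as many (highest 16), so chance was not excluded.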
